A study of Homo sapiens with 12 samples.

How the data were processed

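Total RNA from U937 cells transduced with an EVI1 vector or the empty vector and treated with TPA or ethanol was measured on 12 Affymetrix U133 Plus 2.0 arrays, 3 per group, with 250 ng of RNA labelled by 3' in vitro transcription, per the labels' protocols. The design text calls the 3 samples of a group biological replicates. That term does not show whether they come from separate transductions. If they do not, tests between the populations measure the spread between cultures and not between transductions. The deposited values are log2 RMA expression values made by the authors in Affymetrix Expression Console 1.3, per the submitters' processing notes. RMA subtracts background, forces the arrays to 1 distribution and summarises the probes of a probe set, so a shift common to most genes is removed from the values. Whether the 12 arrays were normalized together is not given in the sources used here, and the array medians lay between 5.07 and 5.11. The values had 2 decimals and ran from 1.98 to 14.6. No detection call was used, so a low value has no stated floor and differences of dim genes are compressed. The lowest array median, taken as the level below which a group mean is not shown to be above background, was chosen after the data were seen. Saturation of the brightest probe sets was not assessed.

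The table held 54675 probe sets, 62 of them controls. The platform annotation given for this work named 1 gene for 41097 probe sets, several for 1801 and none for 11777, and only the first kind was used. Each of 19775 genes was given the probe set with the highest mean over the 12 arrays, and 10523 genes had more than 1. Symbols were checked against a RefSeq gene table, which lacked 40 of the genes and otherwise served only for the order of genes along chromosomes. Another probe set was called in the opposite direction for 173 of 5381 called genes with several probe sets for TPA in empty vector cells, 140 of 5046 for TPA in EVI1-labelled cells, 1 of 441 between populations in ethanol, 2 of 1437 in TPA and 0 of 257 for the difference in response.

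Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 12 arrays, empirical Bayes moderation (8 residual and 5.22 prior degrees of freedom), two-sided tests and Benjamini-Hochberg adjustment at 0.05 over all genes. The comparisons were TPA against ethanol in each population, EVI1-labelled against empty vector cells in each treatment, the difference between the responses, and both averaged effects. The number of arrays sets the precision, and the median SE was 0.11 for a simple comparison, 0.15 for the difference in response and 0.07 for an averaged effect. On simulated data with 200 genes changed at each size among 19775, a simple comparison recovered 71.5%, 98% and 100% of changes of 0.5, 1 and 2 on the log2 scale with 4.77% false calls, and the difference in response 34.5%, 87% and 100% with 3.28% false calls.

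The groups, tests, gene lists, rule for named genes and alternatives were fixed before the data were examined. The 22 gene lists had 502 entries, of which 451 were measured: monocyte and macrophage, NF-kB and inflammatory, AP-1 and immediate early, cell cycle, MYC and ribosome biogenesis, primary granule, CDK inhibitor and cell cycle exit, BCL2 family, interferon response, cholesterol synthesis, adhesion and matrix proteolysis, lysosome, EVI1-linked, stem and progenitor, myeloid transcription factor, phorbol ester receptor, glycolysis and hypoxia and MHC class II genes, and markers of erythroid, megakaryocyte, lymphoid, and epithelial and fibroblast cells. The list called primary granule also holds genes of secondary and eosinophil granules, such as LTF and PRG2. The lists were tested with camera at an inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists within each comparison. Named genes were, for each simple comparison, up to 12 with the largest rise and 12 with the largest fall among called genes whose 2 groups did not overlap and whose higher group mean exceeded the median of all genes, 6.12, and for the difference in response up to 10 each way without the overlap condition. MECOM, MS4A3, CDKN1A and up to 2 raised and 2 lowered members of each list were added. IKBKB was chosen after its values were seen. The text names part of these genes and summarises the rest.

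Replicate numbers are shared between groups in the labels. Arrays of the same number correlated in their deviations from the group means at 0.415, 0.130 and 0.151 between the TPA-treated populations, each over 0.1, and in no other pair of groups did all 3 numbers pass 0.1. By this cutoff the numbers were taken to pair the samples for the comparison of populations in TPA only, from the data and not from a stated shared day. In 14 of 18 same-number pairs the correlation was above those with the other numbers. This held for every number in every simple comparison, at 0.075 to 0.208 outside the comparison of populations in TPA. The exceptions lay between groups that differ in both vector and treatment. The numbers may therefore pair the arrays in all simple comparisons, and the cutoff of 0.1 does not show otherwise. The main fit ignores the numbers in all comparisons, and only the block among the alternatives takes them up.

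The alternatives were the replicate number as a block, only the groups compared in the fit or array weights, genes with a mean below the median left out, the mean of probe sets or all probe sets in place of 1 per gene, an intensity trend with robust moderation, median centring, a further quantile normalization, a minimum log2 difference of 1, and each array left out in turn. Leaving out genes in runs of shifted neighbours, for the gene counts and all 22 lists, was chosen after seeing the data, as was leaving out both TPA arrays of a replicate number for the lists between populations in TPA and for the difference in response. Splits of the population labels were also run with each gene's averaged population difference subtracted, and that step was tested on simulated data. Neighbour runs were sought among 9870 genes with a mean above the median, as windows of 15 genes whose absolute median difference between populations exceeded the 95th percentile of the largest in 1000 shuffles of gene order. Exact permutation tests compared 3' to 5' signal gaps. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.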

Results

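RNA levels were measured in U937, an established human myelomonocytic cell line, after transduction with a vector carrying EVI1 or with the empty vector. EVI1 is a zinc finger transcription factor encoded at the MECOM locus. Each population received 50 ng/ml TPA, a phorbol ester that activates protein kinase C and drives U937 cells toward a macrophage-like state, or its solvent ethanol, for 24 h. This gave 4 groups of 3 arrays, described in the labels as biological replicates, and 12 arrays in all. Whether the replicates were transduced separately is not shown, so p-values between the populations may not cover the spread between transductions. The design asks what TPA changes in each population, what differs between the populations in each treatment, and whether the response to TPA differs between them. Values are log2 probe set signals. Differences are given as log2 with the standard error (SE) of the fit, and group levels as mean ± SD with n = 3. Adjusted p-values come from limma with Benjamini-Hochberg adjustment over 19775 genes unless another test is named. The number of arrays limits the precision, and the median SE was 0.11 for a difference between 2 groups and 0.15 for a difference between responses. Within groups the arrays correlated at 0.993 to 0.998. No detection call was used, so a group mean below 5.07, the lowest array median, is not shown to be above background, and a difference that involves one has an uncertain size. This held in at least 1 group for 66 of the 161 genes behind the named results.

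The EVI1 transcript was looked at before any other gene. The 5 probe sets that name MECOM read between 2.59 and 3.32 on the 12 arrays, which placed them at or below the 13.7th percentile of all probe sets. None differed between the populations in either treatment, the smallest adjusted p being 0.118. The 5 probe sets may lie outside the part of the transcript that the vector expresses, and their place was not compared with the vector. Whether their readings go against the labels is therefore open, and expression of EVI1 is not shown here. The transduced population is called EVI1-labelled throughout.

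In empty vector cells, 24 h of TPA raised genes of macrophage biology and lowered the genes of the dividing cell by large amounts. SPP1, which encodes the secreted matrix protein osteopontin, rose by 9.56 ± 0.53 (SE), from 4.99 ± 1.59 to 14.55 ± 0.05 (SD, n = 3). The latter level is close to the highest value in the table, and saturation was not assessed, so the size of this rise is uncertain. FABP4, a lipid-binding protein of adipocytes and macrophages, rose by 8.11 ± 0.24, and IL1B, the inflammatory cytokine interleukin 1 beta, by 8.09 ± 0.28. At the other end, CDCA7 fell by 6.44 ± 0.38, E2F8, a transcription factor of the cell cycle, by 6.12 ± 0.22, MCM10, a DNA replication factor, by 6.10 ± 0.28, and MS4A3, a membrane protein of myeloid progenitors, by 5.88 ± 0.24. The 12 genes with the largest rises under the fixed rule lay between 7.24 and 9.56 and included ZFP36L1, TDO2, IL7R, GDF15, CD52, PHLDA1, the complement receptor gene C5AR1 and HAVCR2. The 12 with the largest falls lay between -6.44 and -5.58, and besides those named they included SPC25, DTL, KIF15, ASPM, KIF20A, NDC80, TTK and HELLS. Of the 12 rises 8 started below the lowest array median and of the 12 falls 11 ended below it, so their sizes and order are uncertain. In all, 8535 genes passed the threshold, 4094 higher and 4441 lower with TPA, and 3054 of them changed by at least 1 on the log2 scale.

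Among the gene lists fixed before the data were examined, all 30 cell cycle genes fell with TPA in empty vector cells, with the mitotic transcription factor FOXM1 at -4.54 ± 0.14 and the replication helicase subunit MCM3 at -4.18 ± 0.13. Of 20 genes of the MYC and ribosome biogenesis list 19 fell, among them MYC by 2.86 ± 0.09 and the RNA polymerase I subunit POLR1B by 1.80 ± 0.08. Of 26 monocyte and macrophage genes 20 rose, including ITGAX, an integrin of myeloid cells, by 4.78 ± 0.14, and 3 fell, including the chemokine receptor CCR2 by 1.90 ± 0.18 and the lysozyme gene LYZ by 1.29 ± 0.15. Of 28 NF-kB and inflammatory genes 22 rose, including the adhesion molecule ICAM1 by 3.95 ± 0.12 and CD83 by 3.56 ± 0.12, and SOD2, a mitochondrial superoxide dismutase, fell by 1.34 ± 0.13. Of 27 AP-1 and immediate early genes 24 rose, MAFF by 6.13 ± 0.16, and 2 fell, BATF3 by 1.65 ± 0.09 and the phosphatase DUSP2 by 1.10 ± 0.19. The counts were the same when adjusted over the list alone for these 5 lists. The camera test called each of them, with adjusted p of 5.51e-19 for the cell cycle, 1.8e-12 for MYC and ribosome biogenesis, 2.95e-08 for monocyte genes, 3.84e-11 for NF-kB genes and 1.24e-13 for AP-1 genes. With an estimated correlation between genes the cell cycle call was lost (adjusted p = 0.133 with an estimated correlation), while the other 4 kept theirs, with adjusted p of 0.0396, 0.0404, 0.0401 and 0.00295.

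Further lists moved in empty vector cells. Of 18 CDK inhibitor and cell cycle exit genes 11 rose and 2 fell (11 and 3 when adjusted over the list alone), with the CDK inhibitors CDKN1A and CDKN2B up by 4.87 ± 0.12 and 5.57 ± 0.19 and CDKN1B down at -1.35 ± 0.13. For CDK inhibitor genes camera gave an adjusted p of 8.35e-04, and 0.0401 with an estimated correlation. Of 26 adhesion and matrix proteolysis genes 19 rose and 1 fell, the same when adjusted over the list alone, among them the urokinase receptor gene PLAUR by 5.01 ± 0.11 and LGALS3, which encodes galectin 3, by 3.06 ± 0.10. For adhesion genes camera gave an adjusted p of 1.65e-09, and 0.0396 with an estimated correlation. Lysosome genes rose in 19 of 25 cases (20 when adjusted over the list alone), with the protease gene CTSH up by 2.64 ± 0.10 and PSAP by 2.16 ± 0.10. For lysosome genes camera gave an adjusted p of 4.68e-09, and adjusted p = 0.169 with an estimated correlation. Interferon response genes rose in 18 of 28 cases and fell in 1 (19 and 1 when adjusted over the list alone), OAS1 by 4.79 ± 0.49 and IRF9 by 2.44 ± 0.20. For interferon genes camera gave an adjusted p of 4.55e-05, and adjusted p = 0.5 with an estimated correlation. Genes of the primary granule list fell in 9 of 17 cases and rose in 2, the same when adjusted over the list alone. The serine protease gene PRTN3 was down at -3.12 ± 0.21. For granule genes camera gave an adjusted p of 0.012, and adjusted p = 0.306 with an estimated correlation. Of 19 stem and progenitor genes 8 fell and none rose, the same when adjusted over the list alone, with the transcription factors MYB and ERG at -4.42 ± 0.14 and -2.22 ± 0.12. For progenitor genes camera gave an adjusted p of 0.0159, adjusted p = 0.0642 with an estimated correlation, and 0.2 with genes below the median mean left out. The signal gap between 3' and 5' probe sets, a sign of RNA integrity and labelling, moved with the treatment: for ACTB it was 1.31 ± 0.17 on the 6 TPA arrays and 1.85 ± 0.13 on the 6 ethanol arrays (exact permutation test, two-sided p = 0.00216). For GAPDH it was 0.40 and 0.57 (exact permutation test, two-sided p = 0.0476).

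The EVI1-labelled cells responded to TPA with most of the same genes. SPP1 rose by 8.92 ± 0.53, FABP4 by 8.78 ± 0.24, ZFP36L1 by 7.96 ± 0.18 and GDF15 by 7.51 ± 0.20, while MCM10 fell by 5.89 ± 0.28 and E2F8 by 5.83 ± 0.22. CDCA7 was at -6.00 ± 0.38. The 12 largest rises lay between 6.86 and 8.92 and also included RGS13, A2M, the immediate early transcription factor EGR3 at 7.30 ± 0.18 and the scavenger receptor CD36 at 7.11 ± 0.23. The 12 largest falls lay between -6.00 and -5.04, with ZNF367, KIF18B and GINS2 among them. Of these rises 9 started and of these falls 9 ended below the lowest array median. In all 7914 genes passed the threshold, 3845 higher and 4069 lower, and 2671 of them changed by at least 1. Across genes the TPA responses of the 2 populations correlated at Pearson's r = 0.955 and Spearman's rho = 0.841, with genes not being independent replicates and the 2 contrasts sharing no array. Of the genes called in both, 6938 changed the same way and 17 the opposite way.

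All 30 cell cycle genes fell in EVI1-labelled cells as well (camera adjusted p = 6.65e-19, and adjusted p = 0.124 with an estimated correlation). So did 19 of 20 MYC and ribosome biogenesis genes (20 when adjusted over the list alone, adjusted p = 1.17e-12, and 0.031 with an estimated correlation). AP-1 and immediate early genes rose in 25 of 27 cases and fell in 1, the same when adjusted over the list alone. For AP-1 genes camera gave an adjusted p of 6.04e-16, and 0.00167 with an estimated correlation. Monocyte and macrophage genes rose in 17 of 26 cases and fell in 2 (17 and 3 when adjusted over the list alone), with C5AR1 at 6.40 ± 0.15 and ITGAX at 4.31 ± 0.14. For monocyte genes camera gave an adjusted p of 9.48e-07, and adjusted p = 0.0673 with an estimated correlation. NF-kB and inflammatory genes rose in 16 of 28 cases and fell in 1, the same when adjusted over the list alone, with CD83 at 3.22 ± 0.12 and ICAM1 at 3.09 ± 0.12. For NF-kB genes camera gave an adjusted p of 1.72e-05, and adjusted p = 0.124 with an estimated correlation. CDK inhibitor genes rose in 12 of 18 cases and fell in 2, the same when adjusted over the list alone (adjusted p = 3.48e-05, and 0.031 with an estimated correlation). Adhesion genes rose in 19 of 26 and fell in 1, the same when adjusted over the list alone (adjusted p = 4.3e-09, and 0.0328 with an estimated correlation). Lysosome genes rose in 17 of 25 cases with none lower (17 higher and 1 lower when adjusted over the list alone, adjusted p = 3.74e-08, and adjusted p = 0.159 with an estimated correlation). Interferon genes rose in 21 of 28 and fell in 1 (22 and 1 when adjusted over the list alone, adjusted p = 1.34e-06, and adjusted p = 0.423 with an estimated correlation). Genes of the primary granule list fell in 10 of 17 cases and rose in 1. Stem and progenitor genes fell in 8 of 19 with none higher, and both lists had the same counts when adjusted over the list alone. In that order camera gave adjusted p of 0.00129 and 0.00848, and adjusted p = 0.159 and 0.0639 with an estimated correlation. With genes below the median mean left out the progenitor list had 0.161. The ACTB and GAPDH gaps given for the treatments cover these arrays too.

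**Figure D1:**
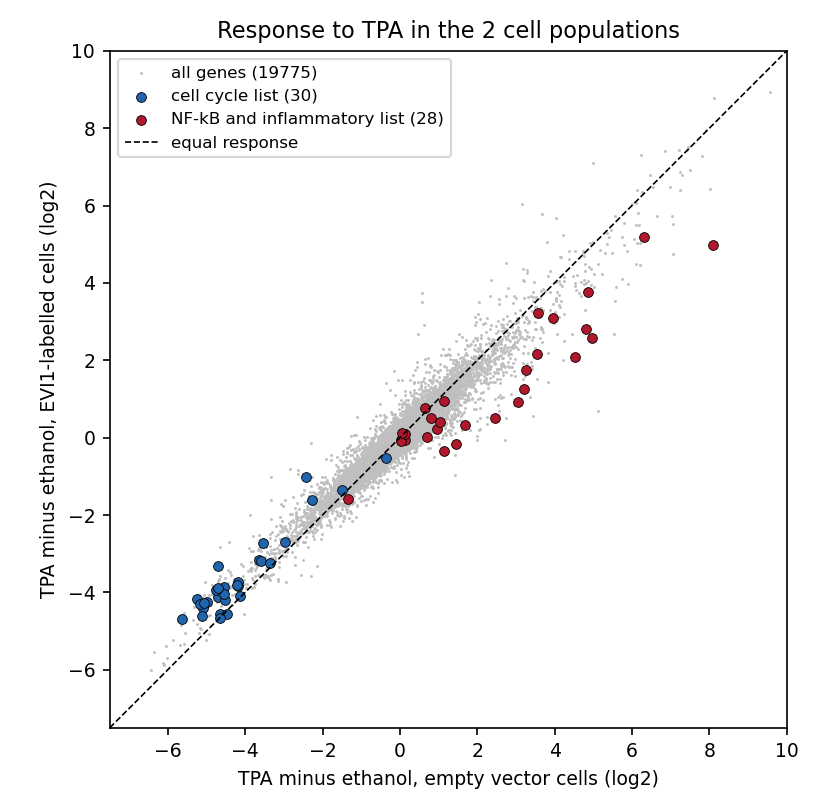
Each point is 1 of 19775 genes, with its TPA minus ethanol difference (log2) in empty vector cells on the horizontal axis and in EVI1-labelled cells on the vertical axis, and the dashed line marks an equal response. The 30 cell cycle genes sit at the lower left near the line, and most of the 28 NF-kB and inflammatory genes lie below the line, with a median difference between the responses of -0.98.

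In ethanol the populations differed in a smaller set of genes, and the largest measured differences were losses. LINC01088, a long noncoding RNA, was at 7.83 ± 0.26 (SD, n = 3) in empty vector cells and 3.24 ± 0.29 in EVI1-labelled cells, a difference of -4.59 ± 0.28 (SE). DNAJC15, a mitochondrial co-chaperone gene, was lower by 4.08 on the log2 scale (-4.08 ± 0.36), TMEM106B, a lysosomal membrane protein gene, at -3.98 ± 0.21, NEO1, which encodes the receptor neogenin, at -2.79 ± 0.17, LTBP1, a latent TGF-beta binding protein gene, at -2.55 ± 0.20 and CADM1, a cell adhesion molecule gene, at -2.53 ± 0.12. The levels of LINC01088, DNAJC15, TMEM106B and CADM1 in EVI1-labelled cells lay below the lowest array median, so the sizes and order of these differences are uncertain. ZNF117 was higher by 2.37 ± 0.22, the nuclear lamina gene LMNB1 by 1.97 ± 0.21, the inhibitory receptor gene CD300A by 1.63 ± 0.16 and RAB13 by 1.50 ± 0.13. FRMD4A was higher by 1.86 ± 0.23. MS4A3 was lower at -1.45 ± 0.24 and CDKN1A higher at 0.74 ± 0.12. Both were named in advance because they had been reported for EVI1 in this cell line. Those reports may rest on these samples, so the 2 values are not independent support. The 12 largest increases spanned 1.23 to 2.37 and the 12 largest decreases -4.59 to -1.47. Among the latter, 5 genes, TMEM106B, NEO1, ASH2L, STAR and RAB11FIP1, lay within runs of neighbouring genes that were lower together in EVI1-labelled cells. The run medians in ethanol were -0.33 for TMEM106B and -0.34 for NEO1, so the shift shared with neighbours is much smaller than these 2 differences. For the others, on chromosome 8, the run median was -0.405, and -0.99 over the 15 neighbours with the largest shift. In all 647 genes passed the threshold, 262 higher and 385 lower in EVI1-labelled cells, with 70 differing by at least 1. The count fell to 378 and 388 without replicate 1 of empty vector or EVI1-labelled cells in ethanol, to 419 and 369 without replicate 2 of each, and to 329 (131 higher, 198 lower) when the genes in such runs were left out. The runs were chosen for differing between the populations, so leaving them out lowers this count by construction.

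Few list members passed in ethanol. Of 13 MHC class II genes 2 were higher, HLA-DRB1 by 0.86 ± 0.17 and HLA-DMA by 0.97 ± 0.20 (4 when adjusted over the list alone, camera adjusted p = 0.00449, and adjusted p = 0.292 with an estimated correlation). Of the 13, 5 lie in 1 run of higher neighbours on chromosome 6. With genes in such runs left out, 8 remained and the adjusted p was 0.11. The run was chosen for being higher in EVI1-labelled cells, so leaving out its genes weakens the list by construction. The loss does not show that the list's difference is regional. Without replicate 2 of empty vector cells in ethanol HLA-DRB1 had an adjusted p of 0.0555, the larger of 2 such losses among the 12 arrays, and HLA-DMA of 0.0732, the largest of 4. Of 18 CDK inhibitor and cell cycle exit genes 2 were higher, CDKN1A with the value above and GADD45A at 0.39 ± 0.09 (3 when adjusted over the list alone, adjusted p = 0.0247, and adjusted p = 0.292 with an estimated correlation). The list missed the threshold without replicate 2 of empty vector cells (0.0561) or replicate 3 of EVI1-labelled cells (0.0641) in ethanol. Without replicate 1 of empty vector cells in ethanol GADD45A had an adjusted p of 0.166, the largest of 7 such losses among the 12 arrays. The MYC and ribosome biogenesis list had a median of -0.14, with 1 of 20 genes lower over all genes and over the list alone, RRS1 at -0.43 ± 0.10. For MYC-list genes camera gave an adjusted p of 0.00449, and adjusted p = 0.418 with an estimated correlation. RRS1 lies in a lower run and its call was lost without 6 of the 12 arrays, with a largest adjusted p of 0.131 without replicate 2 of empty vector cells in ethanol. The 28 NF-kB and inflammatory genes had a median of 0.05 and the 30 cell cycle genes of -0.08 in ethanol, and neither list passed camera (adjusted p = 0.348 and 0.383). Of 17 genes linked to EVI1 in earlier work, a list that includes MS4A3 and may in part rest on these samples, 1 was higher and 2 lower (1 and 5 when adjusted over the list alone, adjusted p = 0.105), among them BCL2L1, a survival gene in a lower run, at -0.45 ± 0.08, whose adjusted p was 0.0516 without replicate 1 of EVI1-labelled cells in ethanol. Of the erythroid, megakaryocyte, lymphoid, and epithelial and fibroblast marker lists, none passed camera between the populations in ethanol, though the B cell transcription factor gene PAX5 was higher by 0.90 ± 0.14 (adjusted p = 0.00182), 1 of 15 lymphoid genes over all genes and over the list alone. The smallest adjusted p was 0.0894, for the lymphoid list. It was 0.0313 without replicate 1 of EVI1-labelled cells and 0.0298 without replicate 2 of empty vector cells in ethanol.

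After TPA the EVI1-labelled cells had less RNA for inflammatory genes than empty vector cells, and for several genes the measured gap was large. CADM1 was at 9.80 ± 0.15 (SD, n = 3) in empty vector cells and 4.48 ± 0.22 in EVI1-labelled cells, a difference of -5.33 ± 0.12 (SE). THBD, the gene of the anticoagulant receptor thrombomodulin, was lower at -4.51 ± 0.33, LTBP1 at -4.43 ± 0.20, the chemokine gene PPBP at -4.42 ± 0.22, IL1B at -2.70 ± 0.28, the fungal receptor gene CLEC7A at -2.52 ± 0.30 and the chemokine gene CCL20 at -2.48 ± 0.18. JAKMIP2 was higher by 4.24 ± 0.11, AKR1C3, an aldo-keto reductase gene, by 3.58 ± 0.19, MB, the myoglobin gene, by 2.92 ± 0.32, LMNB1 by 2.89 ± 0.21 and ZNF117 by 2.86 ± 0.22. The sizes are uncertain for CADM1, THBD and PPBP, whose levels in EVI1-labelled cells lay below the lowest array median, and for JAKMIP2 and AKR1C3, whose levels in empty vector cells did. FRMD4A, higher by 0.83 ± 0.23 here, read 0.04 with the mean of its probe sets (adjusted p = 0.884), and its call was also lost without 3 of the 12 arrays, with a largest adjusted p of 0.123 without replicate 2 of TPA-treated empty vector cells. The largest increases also included RASD2, GPR18, ATL1, NREP, ATP9A and ACAT2, and the 12 spanned 1.78 to 4.24, while the 12 largest decreases spanned -5.33 to -2.48. In all 2214 genes passed the threshold, 1166 higher and 1048 lower, and 313 of them differed by at least 1. With only the 6 TPA arrays in the fit the count was 1241.

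By list, 18 of 28 NF-kB and inflammatory genes were lower in EVI1-labelled cells after TPA and none was higher, the same when adjusted over the list alone, with OSM, the cytokine oncostatin M, at -2.07 ± 0.14. For NF-kB genes camera gave an adjusted p of 7.95e-19, and 0.035 with an estimated correlation. Of 26 monocyte and macrophage genes 13 were lower and 2 higher (14 and 2 when adjusted over the list alone), with the pattern recognition receptor genes TLR2 and CD14 both at -1.70 and SE of 0.17 and 0.19, and CD36 higher by 1.21 ± 0.23. For monocyte genes camera gave an adjusted p of 6.7e-07, and adjusted p = 0.107 with an estimated correlation. Of 17 genes of the primary granule list 7 were lower and 1 higher (7 and 2 when adjusted over the list alone). The eosinophil granule genes PRG2 and RNASE2 were at -1.47 ± 0.20 and -1.38 ± 0.21. The primary granule gene MPO went the other way, with means of 5.38 in empty vector and 5.81 in EVI1-labelled cells. For granule genes camera gave an adjusted p of 0.00328, and adjusted p = 0.364 with an estimated correlation. CDK inhibitor and cell cycle exit genes were higher in 6 of 18 cases with none lower (7 when adjusted over the list alone), GADD45B by 0.52 ± 0.07 and CCNG2 by 0.90 ± 0.15. For CDK inhibitor genes camera gave an adjusted p of 0.00202, and adjusted p = 0.107 with an estimated correlation. Cell cycle genes were higher in 6 of 30 cases with none lower (8 when adjusted over the list alone), CCNB2, which has a further probe set called the other way for TPA in empty vector cells, by 1.40 ± 0.11 and the mitotic factor FOXM1 by 0.70 ± 0.14. For cell cycle genes camera gave an adjusted p of 1.97e-04, and adjusted p = 0.589 with an estimated correlation. That list's median level was 7.92 on replicate 1 of EVI1-labelled and 7.21 on replicate 1 of empty vector cells against 6.30 to 6.60 on the other 4 TPA arrays, and without the former array the adjusted p was 0.485. Within replicate numbers 1, 2 and 3, which pair the TPA arrays, the median was higher in EVI1-labelled cells by 0.71, 0.295 and 0.12. With both TPA arrays of replicate 1 left out, a setting chosen after the data were seen, the adjusted p was 1.02e-06 at the preset correlation. That setting removes the largest of the paired differences and the arrays furthest from their groups, so the smaller value does not show a larger difference.

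Cholesterol synthesis genes were higher in 6 of 17 cases and lower in 1 after TPA (10 and 1 when adjusted over the list alone), with ACAT2 at 1.78 ± 0.19, in a run of higher neighbours on chromosome 6, and HMGCS1, which encodes HMG-CoA synthase, at 0.69 ± 0.12. For cholesterol genes camera gave an adjusted p of 1.97e-04, and adjusted p = 0.482 with an estimated correlation. Of 13 MHC class II genes 4 were higher (5 when adjusted over the list alone), HLA-DMA by 1.45 ± 0.20. For class II genes camera gave an adjusted p of 0.00178, adjusted p = 0.139 with an estimated correlation, and 0.0352 without genes in shifted runs. Of 19 stem and progenitor genes 4 were higher and none lower, the same when adjusted over the list alone, with MYB at 1.68 ± 0.14, or 3.20-fold. For progenitor genes camera gave an adjusted p of 0.0293, adjusted p = 0.133 with an estimated correlation, 0.12 with the mean of probe sets, 0.073 without replicate 3 of TPA-treated EVI1-labelled cells, and 0.0564 without both TPA arrays of replicate 1. Of 28 interferon response genes 2 were higher (1 when adjusted over the list alone), GBP1 by 2.26 ± 0.41 and RSAD2 by 1.40 ± 0.42, with a list adjusted p of 0.0453 that was 0.0518 with the replicate number as a block, 0.479 with genes below the median mean left out and 0.819 with an estimated correlation. The call rested on replicate 3 of TPA-treated EVI1-labelled cells, where the list's median level was 9.12 against at most 7.58 on the other 5 TPA arrays. Without it the direction turned and the adjusted p was 0.422. Within replicate numbers the median differed by -0.215, -0.22 and 2.12, and without both TPA arrays of replicate 3 the list was lower in EVI1-labelled cells at an adjusted p of 8.33e-04. It was 0.486 without only replicate 3 of TPA-treated empty vector cells and 0.0517 without replicate 2 of empty vector cells in ethanol. RSAD2 lost its call without 9 of the 12 arrays, with a largest adjusted p of 0.115 without replicate 2 of TPA-treated empty vector cells.

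Adhesion and matrix proteolysis genes, 2 of 26 higher and 5 lower (2 and 6 when adjusted over the list alone), had a camera adjusted p of 0.0589, 0.0449 with the replicate number as a block, and 0.0406 without genes in shifted runs. It was 0.0228 and 0.0333 without replicate 1 of TPA-treated or replicate 3 of ethanol-treated empty vector cells, 0.00885 and 0.041 without replicate 2 or 3 of TPA-treated EVI1-labelled cells, and 0.0442 without both TPA arrays of replicate 3. Glycolysis and hypoxia genes, 1 of 27 higher and 3 lower (3 and 5 when adjusted over the list alone), had 0.0944, and 0.0457 with the block, 0.0337 without replicate 3 of TPA-treated EVI1-labelled cells, or 0.0358 without both TPA arrays of that number. Of the 17 genes linked to EVI1, 2 were higher and 3 lower, the same when adjusted over the list alone (adjusted p = 0.689), with GFI1 at 1.20 ± 0.15 and BCL2L1 at -0.86 ± 0.08. None of the 4 marker lists of other cell types passed camera in TPA, but single members passed limma, the same when adjusted over the list alone. Of 10 megakaryocyte genes 2 were lower, PPBP with the value above and VWF, the von Willebrand factor gene, at -0.40 ± 0.12 (adjusted p = 0.0427). Of 15 lymphoid genes 1 was higher, PAX5 by 0.68 ± 0.14 (0.00492), and 1 lower, the adhesion molecule gene NCAM1 at -0.30 ± 0.08 (0.036). The VWF call was lost with the mean of its probe sets (0.225) and without 8 of the 12 arrays, with a largest adjusted p of 0.165 without replicate 2 of TPA-treated EVI1-labelled cells. NCAM1 lost its call without 6, with a largest of 0.11 without replicate 3 of TPA-treated empty vector cells.

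Effects of the population in ethanol and in TPA correlated across genes at Pearson's r = 0.436 and Spearman's rho = 0.266, with no array shared. Of the genes called in both treatments 175 were higher in both and 241 lower in both in EVI1-labelled cells, where independent lists would share 15.4 and 20.4, and 9 were called in opposite directions. Averaged over the treatments, 2253 genes differed between the populations, 1108 higher and 1145 lower, and averaged over the populations TPA changed 9488 genes, 4661 higher and 4827 lower. The averaged effects of TPA and of the population, which are orthogonal contrasts, correlated at r = -0.09. Genes called for both were 439 higher in both, 556 raised by TPA and lower in EVI1-labelled cells, 475 lowered by TPA and higher in EVI1-labelled cells, and 395 lower in both, beside 261.2, 269.9, 270.5 and 279.5 for independent lists. Each count was above its number for independent lists, opposed directions included. Those numbers, here and for ethanol and TPA, take every tested gene as equally likely to be called. An excess alone therefore does not show that the effects are related.

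The test of the difference itself showed which genes responded to TPA differently in the 2 populations. PPBP read 5.11 ± 0.22 (SE) for TPA in empty vector cells and 0.70 ± 0.22 in EVI1-labelled cells, a difference of -4.41 ± 0.31 (adjusted p = 1.5e-05). IL1B rose by 8.09 and by 4.97 (difference -3.12 ± 0.40, adjusted p = 0.00134), CCL20 by 4.53 and 2.10 (-2.43 ± 0.25). The chemokine gene CCL4 rose by 4.96 and 2.58 (-2.38 ± 0.42), and CLEC7A by 4.48 and 2.00 (-2.48 ± 0.43). CADM1 rose by 2.72 ± 0.12 in empty vector cells and read -0.07 ± 0.12 in EVI1-labelled cells (difference -2.80 ± 0.17, adjusted p = 3.2e-06), and the monocyte marker CD14 rose by 2.00 ± 0.19 and read -0.06 ± 0.19 (difference -2.06 ± 0.28). In the other direction AKR1C3 went up by 3.75 ± 0.19 in EVI1-labelled cells against 0.56 ± 0.19 (difference 3.19 ± 0.27), JAKMIP2 by 3.50 against 0.56 (2.94 ± 0.15). MB rose by 6.05 against 3.17 (2.88 ± 0.46) and CD36 by 7.11 against 4.98 (2.13 ± 0.32). MYB fell by 2.69 ± 0.14 in EVI1-labelled cells and by 4.42 ± 0.14 in empty vector cells, a difference of 1.73 ± 0.20 (adjusted p = 6.6e-04). The levels of PPBP lay below the lowest array median in all groups but TPA-treated empty vector cells, those of JAKMIP2 and AKR1C3 in all but TPA-treated EVI1-labelled cells, and that of CADM1 in EVI1-labelled cells in both treatments. CCL4, CLEC7A and MB lay below it in ethanol in both populations, and CD14 in empty vector cells in ethanol and EVI1-labelled cells in TPA. The sizes of these responses and of their differences are therefore uncertain. The rise of PPBP in EVI1-labelled cells was not past the threshold without 3 of the 12 arrays, with a largest adjusted p of 0.0979 without replicate 3 of TPA-treated EVI1-labelled cells, and that of AKR1C3 in empty vector cells without 3, with a largest of 0.143 without replicate 3 of TPA-treated empty vector cells.

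**Figure D2:**
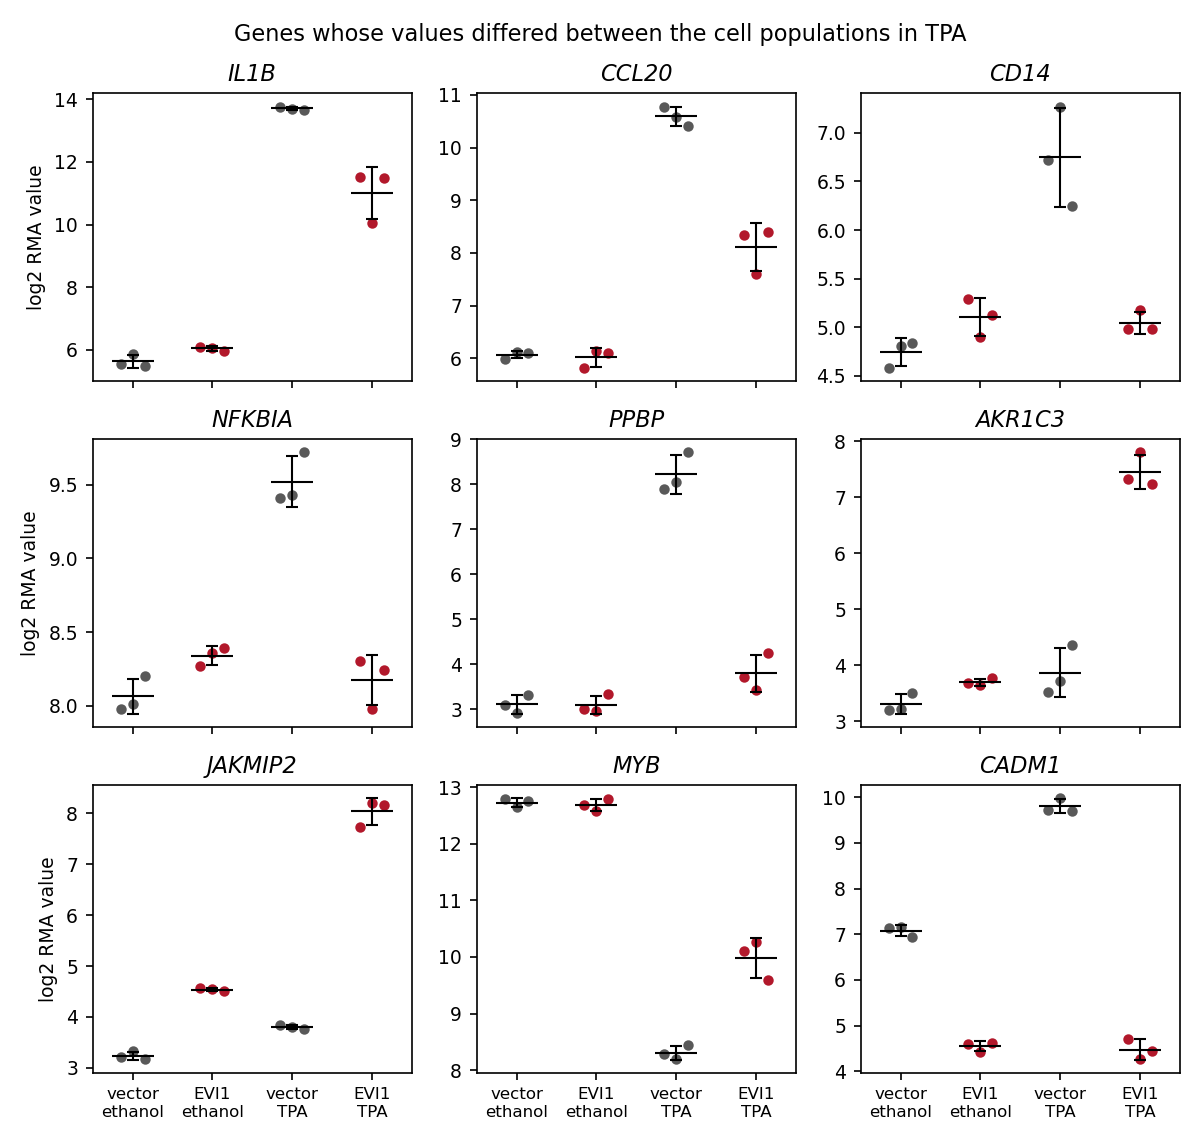
Levels of 9 genes (log2 signal, vertical axes) on each of the 12 arrays, by group, with points for arrays, horizontal bars for group means and vertical bars for the SD over n = 3. PPBP averages 8.22 in TPA-treated empty vector cells and 3.80 in TPA-treated EVI1-labelled cells, and JAKMIP2 averages 3.80 and 8.04.

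In all 392 genes responded differently, 185 with a positive and 207 with a negative difference, EVI1-labelled minus empty vector. Of the 364 that were also called for the averaged TPA effect, 256 (70.3%, jackknife SE over arrays 13.2) had a smaller response in EVI1-labelled cells, 74 a larger one and 34 an opposite one. Over all genes called for the averaged TPA effect, the absolute response was smaller in EVI1-labelled cells for 56.1% of raised and 70.8% of lowered genes. The count depended on single arrays. It was 188, 253 and 193 without replicate 1, 2 or 3 of empty vector cells in ethanol, 195, 214 and 195 without replicate 1, 2 or 3 of EVI1-labelled cells in ethanol, 244 without replicate 2 of TPA-treated EVI1-labelled cells and 681 without their replicate 3, and 617 with array weights.

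Of 28 NF-kB and inflammatory genes 16 had a smaller or more negative response in EVI1-labelled cells and none a larger one (17 when adjusted over the list alone), with a median difference of -0.98. NFKBIA, the gene of the NF-kB inhibitor IkB alpha, rose by 1.46 ± 0.11 in empty vector cells and read -0.17 ± 0.11 in EVI1-labelled cells (difference -1.62 ± 0.15), and OSM rose by 3.21 and 1.25 (difference -1.97 ± 0.20). The list passed camera at adjusted p = 2.51e-25, and at 0.0136 with an estimated correlation. Of 26 monocyte and macrophage genes 5 had a negative and 2 a positive difference (9 and 3 when adjusted over the list alone), TLR2 at -1.67 ± 0.23 being among the former. For monocyte genes camera gave an adjusted p of 1.44e-04, and adjusted p = 0.312 with an estimated correlation. Cholesterol synthesis genes had a positive difference in 5 of 17 cases (9 when adjusted over the list alone), ACAT2 at 1.51 ± 0.27 and HMGCS1 at 0.97 ± 0.17. For cholesterol genes camera gave an adjusted p of 9.39e-08, and adjusted p = 0.325 with an estimated correlation. The cell cycle list had a median of 0.50, with 1 of 30 genes past the threshold (2 when adjusted over the list alone), CCNB2 at 1.40 ± 0.16, a value of 0.34 with the mean of its probe sets. For cell cycle genes camera gave an adjusted p of 9.87e-06, adjusted p = 0.611 with an estimated correlation, and 0.102 without replicate 1 of TPA-treated EVI1-labelled cells. With both TPA arrays of replicate 1 left out, chosen after the data were seen, it was 2.23e-10 at the preset correlation. That setting removes the arrays furthest from their groups, so the smaller value does not show a larger difference or restore the lost call.

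Another 3 lists passed camera for the difference in response with small medians. The lysosome list had a median of -0.12 with no gene past the threshold of limma and 9 of 25 at an unadjusted p under 0.05 (1 lower when adjusted over the list alone, adjusted p = 0.0278, and adjusted p = 0.703 with an estimated correlation). It was lost without any of replicate 1 (0.183) or 2 (0.0717) of TPA-treated EVI1-labelled cells, 2 (0.0677) or 3 (0.108) of TPA-treated empty vector cells, or 3 of empty vector (0.121) or EVI1-labelled cells in ethanol (0.13), and without both TPA arrays of replicate 2 (0.121). MYC and ribosome biogenesis genes had a median of 0.15 with no gene past the threshold of limma over all genes or over the list alone and 1 of 20 at an unadjusted p under 0.05 (adjusted p = 0.0178, and adjusted p = 0.611 with an estimated correlation). The call was lost with genes below the median mean left out (0.126) and without replicate 1 of TPA-treated EVI1-labelled cells (0.183), replicate 2 of TPA-treated empty vector cells (0.0797) or replicate 3 of EVI1-labelled cells in ethanol (0.0606). Myeloid transcription factors had a median of 0.16, with 4 of 26 positive and 1 negative (7 and 2 when adjusted over the list alone), among them GFI1, a transcriptional repressor, at 1.35 ± 0.22. For these factors camera gave an adjusted p of 0.0473, and adjusted p = 0.289 with an estimated correlation. That call was lost with genes below the median mean left out (0.447), without genes in shifted runs (0.131), and without replicate 1 of empty vector cells in ethanol (0.0941), replicate 3 of EVI1-labelled cells in ethanol (0.067), replicate 2 (0.0677) or 3 (0.108) of TPA-treated empty vector cells, or replicate 1 (0.0622) or 3 (0.0855) of TPA-treated EVI1-labelled cells, and without both TPA arrays of replicate 2 (0.0624) or 3 (0.125).

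Some differences between the populations were shared by neighbouring genes. Among 9870 genes with a level above the median, placed in gene order, the running median of 15 neighbours for the difference averaged over the treatments reached -1.05 on chromosome 8, between ADGRA2 and TM2D2, with 15 of 15 genes lower in EVI1-labelled cells. It was -0.99 in ethanol and -1.11 in TPA. In 1000 shuffles of the gene order the largest absolute median was 0.405, and the limit, the 95th percentile of the largest, was 0.288. Past that limit lay 17 runs with 611 genes, of which 407 were called for the averaged difference.

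**Figure D3:**
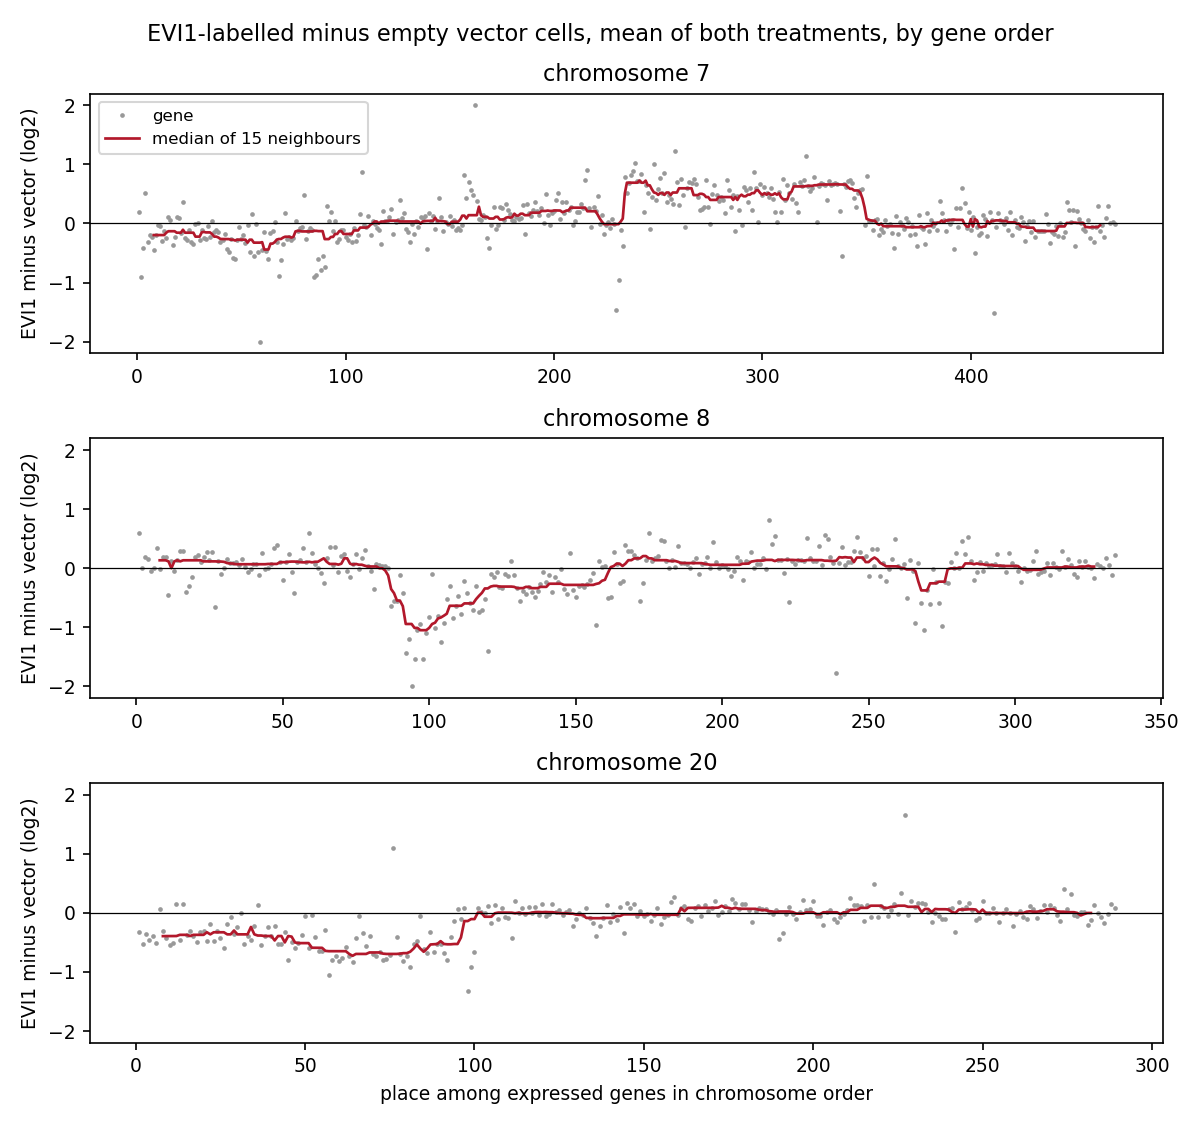
The difference between EVI1-labelled and empty vector cells averaged over both treatments (log2, vertical axes) against the place of each expressed gene in the order of chromosomes 7, 8 and 20 (horizontal axes), with grey points for genes, a line for the running median of 15 neighbours, and 3 genes with an absolute difference above 2 drawn at 2 or -2. The longest run past the shuffle limit on each holds 129 genes on chromosome 7 with a median of 0.52, 68 on chromosome 8 with -0.41 and 103 on chromosome 20 with -0.47. A further run holds 28 genes on chromosome 7 with a median of -0.30, and another 17 on chromosome 8 with -0.26.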

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

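All tests below were planned before their results were seen except the splits with the averaged population effect removed, chosen after the result without that step was seen.

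The response to TPA differed between the populations for 392 genes by limma's test of the difference. In 100 drawn splits of the population labels within treatments, 6 gave as many, the real one included, and the highest other gave 2253. The other 5 keep the TPA labels whole and swap at least 2 of the 3 ethanol labels, a structure that turns the difference between populations into a difference in response, so these splits decide nothing about chance. The highest count without that structure was 279. With each gene's averaged population difference subtracted first, 1 of the same 100 splits, the real one, reached 392 and the highest other gave 31. The difference subtracted was itself estimated with the real labels, which takes from the other splits what had raised their counts. That step was chosen after the first result, so it does not exclude chance. For TPA averaged over the populations 1 of 100 splits, the real one, reached 9488 genes, the highest other being 3983. For the populations averaged over the treatments 1 of 100 reached 2253, the highest other being 584. For these 2 counts the share is under 0.05, which argues against chance in how these arrays fell into groups. The splits were drawn without regard to the replicate numbers, so they do not exclude it. They also cannot measure the spread between separate transductions with the same vector. For the 4 simple comparisons the 10 splits of 6 arrays are too few for a share under 0.05: the real split, 1 in each case, gave 8535, 7914, 647 and 2214 genes and the highest other 0, 0, 0 and 2. Among the 3 other splits that part all 3 pairs of the same replicate number, the highest gave 0, 0, 0 and 2.

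Named genes with a more negative response in EVI1-labelled than in empty vector cells by the test of the difference (log2) were PPBP at -4.41, IL1B at -3.12, COL22A1 at -2.88, PINLYP at -2.86, CADM1 at -2.80, CLEC7A at -2.48, CCL20 at -2.43, AFDN at -2.41, ADORA3 at -2.39. Further ones were CCL4 at -2.38, THBD at -2.32, CD14 at -2.06, OSM at -1.97, RASGRP3 at -1.92, LTBP1 at -1.88, CD300A at -1.70, TLR2 at -1.67, NFKBIA at -1.62, IPCEF1 at -1.48, BCL2 at -1.09, KIT at -0.90, ICAM1 at -0.86, CDKN1A at -0.81, PLAUR at -0.77 and BHLHE40 at -0.61. Those with a more positive one were AKR1C3 at 3.19, JAKMIP2 at 2.94, MB at 2.88, RASD2 at 2.22, LINC01088 at 2.16, CD36 at 2.13, SERPINI1 at 2.10, KCNQ5 at 1.87. Further ones were ANKRD55 at 1.84, KMO at 1.78, MYB at 1.73, NREP at 1.70, DUSP2 at 1.63, ACAT2 at 1.51, CCNB2 at 1.40, GFI1 at 1.35, CCR2 at 1.35, ATL1 at 1.08, EGR3 at 1.07, STARD4 at 1.02, HMGCS1 at 0.97, BCL2L11 at 0.95, CEBPA at 0.93, ID1 at 0.82, FDPS at 0.70, SMAD3 at 0.67, RASGRP2 at 0.65 and GADD45B at 0.62. Of these 53 genes 22 had a group mean below 5.07, the lowest array median, which is not shown to be above background, so the sizes are uncertain. For 4 of them, LINC01088, CCR2, KIT and ANKRD55, which were lower with TPA, such a level in both treatments of 1 population or in TPA in both limits the fall, and a difference in response is not shown. A difference in response can also lie in the ethanol levels. In TPA, CD300A read 10.98 in empty vector and 10.91 in EVI1-labelled cells, and CDKN1A 12.64 and 12.57. In ethanol CD300A read 5.39 and 7.02, and CDKN1A 7.78 and 8.51. Lists past camera's threshold had medians of -0.34 for monocyte, -0.98 for NF-kB, 0.50 for cell cycle, 0.15 for MYC and ribosome biogenesis, 0.58 for cholesterol, -0.12 for lysosome and 0.16 for myeloid transcription factor genes. With an estimated correlation the NF-kB list kept its call (adjusted p = 0.0136 with an estimated correlation) and the other 6 lost theirs, with adjusted p of 0.312, 0.611, 0.611, 0.325, 0.703 and 0.289 in the order given.

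Of these 53 gene calls 37 held without each of the 12 arrays, and 16 were lost without 5 to 10 of them. The largest adjusted p was reached without replicate 1 of empty vector cells in ethanol for BCL2L11 (0.0989), KIT (0.0931), ID1 (0.0907), STARD4 (0.0815), SMAD3 (0.0766), BHLHE40 (0.0726), CDKN1A (0.0702) and FDPS (0.0653). It was reached without replicate 3 of that group for PLAUR (0.0806) and IPCEF1 (0.0695). Among EVI1-labelled cells in ethanol it was reached without replicate 1 for ICAM1 (0.0683), replicate 2 for EGR3 (0.123), RASGRP2 (0.09) and KMO (0.0822), and replicate 3 for THBD (0.0656) and CEBPA (0.059). With the mean of probe sets the adjusted p was 0.22 for CCR2, 0.239 for CCNB2, 0.0858 for AFDN, 0.13 for BCL2, 0.053 for NREP, 0.285 for BHLHE40, 0.0532 for SMAD3 and 0.0524 for EGR3.

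NF-kB and inflammatory genes rose less with TPA in EVI1-labelled cells. A generally weaker response is argued against by the 22 TPA-induced members, whose median difference was -1.38 where 10000 random lists of induced genes matched on the averaged TPA effect had a median of -0.10 and a 2.5th percentile of -0.31. A single deciding array is argued against by the largest adjusted p without any 1 array, 2.16e-22, and the choice of probe set by a median of -0.78 (median SE 0.17) over the list with the mean of probe sets. An effect of the EVI1 vector may account for the pattern, as a hypothesis found and tested on the same data, and so may any other difference between the 2 populations, which the design does not separate from the vector. IKBKB, an NF-kB pathway kinase gene chosen after its values were seen, lay in a run of lower neighbours on chromosome 8 and read -0.71 in ethanol and -0.83 in TPA, and its part in the pattern was not tested.

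Genes that differed between the populations in both treatments lay near each other. The largest absolute median of 15 neighbours was 1.05, against a highest of 0.405 in 1000 shuffles. All 359 windows past the limit had 1 sign in both treatments, which their choice by the averaged difference makes likely. The averaged TPA effect also passed its own limit of 1.355, with a largest of 1.42 and 8 windows. Adjacent genes correlated at Spearman's rho = 0.25 in the averaged population difference and at 0.096 in the averaged TPA effect. Passing the limit therefore does not by itself point to copy number. Copy number that differs between the transduced populations may account for runs in the population difference. So may neighbours regulated together, as in the run that holds 5 of 13 MHC class II genes. The run with the class II genes holds 19 genes. The longest holds 129 on chromosome 7, where 97 were called higher and 4 lower, with medians of 0.47 in ethanol and 0.56 in TPA. Another holds 103 on chromosome 20, where 76 were called lower and 1 higher, with -0.43 and -0.42. Joint regulation of a few neighbours is argued against by the length of these long runs. For shorter runs both stay open, and copy number is not shown, since DNA was not measured here. Of the 80 genes placed in the order that differed by at least 1 on the averaged scale, 30% lay in shifted runs of the same sign, a share that decides neither that most do nor that few do.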

How the results depend on the processing

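The alternatives without genes in shifted runs and without both TPA arrays of a replicate number were chosen after the data were seen, and the others were planned. Of the gene counts, correlations and numbers of lists, those with other values were as follows, and the cause was not tested unless the setting itself changes the number of genes or arrays. With all probe sets tested, more features passed: 18615 (8791 higher, 9824 lower) for TPA in empty vector cells, 16933 (7973, 8960) in EVI1-labelled cells, 3830 (1884, 1946) between populations in TPA, 21838 (10423, 11415) for averaged TPA and 3830 (1755, 2075) for the averaged populations. With a minimum log2 difference of 1 the counts were 3054 (1466, 1588), 2671 (1327, 1344), 70 (20, 50) in ethanol, 313 (130, 183), 164 (64, 100) for the difference in response, 2850 (1386, 1464) and 108 (38, 70). With only the groups compared, 396 genes were higher in ethanol and 1241 (626, 615) differed in TPA. Array weights gave 617 (319 higher) for the difference in response. Without genes in shifted runs, which were chosen for differing between the populations, 329 (131, 198) differed in ethanol. With genes below the median mean left out r was 0.970 for the TPA effects and 0.531 for the population effects. With an estimated correlation 6, 4, 0, 1 and 1 lists passed in the 4 simple comparisons and the difference in response, and 4 and 0 for averaged TPA and populations. Leaving out 1 array gave 369 to 787 genes in ethanol (147 to 324 higher, 219 to 463 lower), 188 to 681 for the difference in response (77 to 344 positive, 101 to 337 negative), r of 0.945 to 0.957 for the TPA effects, and 2 to 5 and 3 to 9 lists in ethanol and for the difference in response. Without replicate 3 of TPA-treated EVI1-labelled cells the interferon list turned direction between populations in TPA (adjusted p = 0.422) and for the difference in response (0.0126). Over all 12 arrays left out in turn its adjusted p ran from 0.000104 to 0.486 and from 0.00791 to 0.835. With genes below the median mean left out 9 list calls were lost: stem and progenitor for TPA in empty vector cells (0.2), in EVI1-labelled cells (0.161) and averaged (0.195), BCL2 for TPA in EVI1-labelled cells (0.0654), interferon between populations in TPA (0.479) and averaged (0.18), cell cycle for the averaged populations (0.122), and MYC (0.126) and myeloid transcription factors (0.447) for the difference in response. The granule list in ethanol was gained (0.0245). With the mean of probe sets 4 were lost, BCL2 for TPA in EVI1-labelled cells (0.0821), stem and progenitor between populations in TPA (0.12) and averaged (0.0767), and cell cycle for the averaged populations (0.0634), and 2 gained, myeloid transcription factors for TPA in EVI1-labelled cells (0.0489) and granule in ethanol (0.0338). Without genes in shifted runs 3 were lost, BCL2 for TPA in EVI1-labelled cells (0.0837), class II in ethanol (0.11) and myeloid transcription factors for the difference in response (0.131). That setting gained 5: myeloid transcription factors for TPA in EVI1-labelled cells (0.037), BCL2 (0.0327) and cholesterol (0.0473) in ethanol, adhesion in TPA (0.0406) and BCL2 for the averaged populations (0.0222). Without 1 array, 32 of 1848 list values were no longer past the threshold, 26 newly past it and 2 turned direction. Without both TPA arrays of replicate 3 the interferon list was lower in EVI1-labelled cells in TPA (0.000833) and negative for the difference in response (4.56e-08), the opposite of its direction with all arrays. It was past the threshold for the difference in response without the pair of replicate 1 (0.0237) or 2 (0.000997). Leaving out a pair also lost stem and progenitor in TPA (0.0564, replicate 1), and lysosome (0.121, replicate 2) and myeloid transcription factors (0.0624 and 0.125, replicates 2 and 3) for the difference in response. Without the pair of replicate 3, adhesion, lysosome (each 0.0442) and glycolysis (0.0358) in TPA and granule for the difference in response (0.0396) were gained. Lists past the threshold in neither setting were counted as the same whatever their sign. With the replicate number as a block 8779, 8123, 729, 2498 and 516 genes passed in the simple comparisons and the difference in response, sharing 8461, 7849, 613, 2168 and 376 with the fit without it. Besides the interferon (0.0518), adhesion (0.0449) and glycolysis (0.0457) lists in TPA, the block gained the cholesterol list for the averaged populations (0.0462) and lost TMEFF2 for TPA in empty vector cells (0.0617), and it changed no other call of a list or named gene. Of 18 same-number pairs 10 correlated over 0.1, from -0.02 to 0.415. For named genes 9857 alternative values of 497 calls gave 9423 on the same side of the threshold, 434 not past it and 0 of opposite sign. The block, the intensity trend, all probe sets, only the groups compared and dim genes left out return the same log2 difference. In those settings the sign could not turn. Dim probe sets limit small differences, since RMA compresses them and no background level was given.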

Other observations

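The tests here were planned except those without genes in shifted runs or without both TPA arrays of a replicate number, chosen after the data were seen, and no explanation is offered. Of 17 BCL2 family genes 9 rose and 5 fell with TPA in empty vector cells (9 and 6 when adjusted over the list alone, camera adjusted p = 0.143). In EVI1-labelled cells 8 rose and 2 fell, the same when adjusted over the list alone (adjusted p = 0.0367, and adjusted p = 0.212 with an estimated correlation). That call was lost without replicate 1 of TPA-treated EVI1-labelled cells (0.0779), with the mean of probe sets (0.0821), without genes below the median mean (0.0654) and without genes in shifted runs (0.0837). BCL2A1, an NF-kB-responsive survival gene, rose by 4.68 ± 0.16 (SE) and 4.01 ± 0.16 in the 2 populations. The BH3-only gene PMAIP1 fell by 1.28 ± 0.10 and 1.25 ± 0.10. After TPA 5 of the 17 were higher in EVI1-labelled cells and 3 lower (6 and 4 when adjusted over the list alone, adjusted p = 0.341). Among them were the BH3-only gene BCL2L11 at 1.00 ± 0.15, BNIP3L at 0.77 ± 0.10 and BCL2 at -0.87 ± 0.14. In ethanol 2 were higher and 1 lower (4 and 1 when adjusted over the list alone, adjusted p = 0.105, and 0.0327 without genes in shifted runs). The list's difference in response had an adjusted p of 0.942.

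Of 22 phorbol ester receptor genes 6 rose and 6 fell with TPA in each population, the same when adjusted over the list alone (adjusted p = 0.839 and 0.988). RASGRP3, a Ras exchange factor with a phorbol ester binding domain, rose by 5.90 ± 0.24 in empty vector and 3.98 ± 0.24 in EVI1-labelled cells, a difference of -1.92 ± 0.33. RASGRP2 fell by 3.08 ± 0.10 and 2.43 ± 0.10. The list's adjusted p was 0.223 and 0.689 between populations in ethanol and in TPA. Of 26 myeloid transcription factors 13 rose and 7 fell in empty vector cells (13 and 8 when adjusted over the list alone, adjusted p = 0.229), with GFI1 at -2.96 ± 0.15. In EVI1-labelled cells 11 rose and 5 fell, the same when adjusted over the list alone, with GFI1 at -1.60 ± 0.15. The adjusted p was 0.058 there, but 0.0459 without replicate 1 in ethanol or 0.0458 without replicate 2 in TPA of these cells, 0.0489 with the mean of probe sets, and 0.037 without genes in shifted runs.

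Other lists did not pass camera for TPA. Of 27 glycolysis and hypoxia genes 8 rose and 11 fell in empty vector cells (8 and 12 when adjusted over the list alone, adjusted p = 0.839). In EVI1-labelled cells 6 rose and 10 fell (7 and 10 when adjusted over the list alone, adjusted p = 0.906). Of 17 cholesterol synthesis genes 4 rose and 6 fell (5 and 6 when adjusted over the list alone, 0.839), and 7 and 4 in EVI1-labelled cells (0.0928). Of 13 MHC class II genes 2 rose and 3 fell (2 and 2 when adjusted over the list alone, 0.937), and 1 and 0 in EVI1-labelled cells (0.932). Of 17 EVI1-linked genes, a list that holds MS4A3, 7 rose and 4 fell (0.354), and 7 and 3 in EVI1-labelled cells (8 and 3 when adjusted over the list alone, 0.0928). The erythroid, megakaryocyte, lymphoid, and epithelial and fibroblast lists had adjusted p of 0.839, 0.121, 0.706 and 0.839 in empty vector cells and 0.906, 0.155, 0.863 and 0.932 in EVI1-labelled cells. Single members passed limma: 1, 3, 3 and 1 genes rose and 1, 0, 2 and 0 fell in empty vector cells (1, 3, 3 and 0, and 1, 0, 2 and 0, when adjusted over the list alone). In EVI1-labelled cells 0, 2, 1 and 0 rose and 1, 0, 1 and 0 fell, the same when adjusted over the list alone. VWF rose by 2.72 ± 0.12 and 2.22 ± 0.12, and PAX5 fell by 2.47 ± 0.14 and 2.69 ± 0.14, in the 2 populations.

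Between the populations in ethanol, KIT, a progenitor receptor gene, was higher in EVI1-labelled cells by 1.10 ± 0.14. The stem and progenitor list had an adjusted p of 0.0894, and of 0.0432 without replicate 2 of EVI1-labelled cells. The primary granule list also had 0.0894. It was 0.0313 without replicate 1 of EVI1-labelled cells in ethanol, 0.026 without replicate 2 of them in TPA, 0.0338 with the mean of probe sets and 0.0245 without genes below the median mean. The interferon list had 0.209, and 0.0218 without replicate 3 of TPA-treated EVI1-labelled cells. The monocyte list had 0.0894 with 4 of 26 genes lower. AP-1 genes had 0.299, cholesterol genes 0.0989 (0.0473, toward lower, without genes in shifted runs), adhesion genes 0.548, lysosome genes 0.305, glycolysis genes 0.299 and myeloid transcription factors 0.223. In TPA the adjusted p was 0.939 for AP-1 genes, 0.891 for MYC and ribosome biogenesis genes and 0.436 for myeloid transcription factors. It was 0.163 for lysosome genes, and 0.0413 without replicate 1 of TPA-treated empty vector or 0.0135 without replicate 3 of TPA-treated EVI1-labelled cells, and 0.0442 without both TPA arrays of replicate 3. The 4 marker lists had 0.77, 0.163, 0.689 and 0.833.

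For the difference in response the megakaryocyte list, which holds PPBP, had an adjusted p of 0.132, and of 0.0462 without replicate 3 of TPA-treated EVI1-labelled cells. The primary granule list had 0.132 as well, 0.0482 without that array, and 0.0396 without both TPA arrays of its number. The AP-1 and EVI1-linked lists each had 0.526 and the phorbol ester receptor list 0.56.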
